A study of Aedes aegypti with 7 samples.

How the data were processed

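The data describe the fat body of adult female yellow fever mosquitoes, Aedes aegypti, of the strain UGAL/Rockefeller. The fat body is the insect tissue that stores nutrients and, after a blood meal, makes yolk proteins that the ovary takes up. Small RNA sequencing covered 5 time points, namely 72 h post eclosion (PE, after the adult emerges) and 6, 24, 36 and 48 h post blood meal (PBM), with 3 libraries at each, 15 in all. AGO1 CLIP-seq covered 72 h PE and 24 h PBM with 3 libraries at each, 6 in all. In CLIP-seq, ultraviolet light links proteins to the RNA they touch, the protein is pulled down with an antibody and the attached RNA is sequenced. AGO1 is an Argonaute protein, which carries microRNAs (miRNAs) to the messenger RNAs they repress. Each of the 7 GEO samples is 1 assay at 1 time point, and its replicates are separate columns of the tables of the whole series. The series' design text calls the replicates independent biological ones, and every n = 3 rests on that statement. Per the labels, females 3 or 4 days old were counted as 72 h PE, and their cage mates were then given blood. No label says that a replicate number marks a cage.

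RNA for the small RNA libraries was extracted with TRIZOL and prepared with the TruSeq small RNA kit, per the labels' protocols. Tissue for CLIP-seq was irradiated with 900 mJ/cm2 of ultraviolet light and precipitated with an antibody against AGO1, per the labels' protocols. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.14, bedtools 2.17.0 and R 3.1.2 without saying what each was used for. The deposited miRNA table holds raw read counts of the 124 mature miRNAs of miRBase release 21 in each library. The same table holds reads scaled to the library total (RPM) made by the authors. In each library the RPM equal the count times 1 constant, and the inverse of that constant corresponds to a whole number of reads, 8558678 to 29670297 per library, which was taken as the total reads. RPM therefore move with everything else in a library as well as with the miRNAs.

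The deposited CLIP-seq table holds counts per peak and library over a common set of peaks, so the replicates could be compared peak by peak. Peak positions are on AaegL3 supercontigs with the AaegL3.3 annotation, per the column explanations deposited with the table, and are given as in the file, which does not state whether positions start at 0 or 1. The same explanations call the total count of a peak a count of barcodes, and it equalled the sum over the 6 libraries for all 100836 peaks. Settings of the peak finder are not given in the sources used here. The annotation class of each peak is the one the authors gave. A table of predicted miRNAs, made by the authors with miRDeep2 on reads pooled over libraries, per the file headers, gives a score and read counts for each prediction. That table is held here in part, and the 201 predictions in it are those analysed.

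Changes in counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM (trimmed mean) library scaling, the filterByExpr filter, the robust quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05 within each comparison. All edgeR, DESeq2 and limma tests are two-sided, and every adjusted p for a gene, peak or miRNA comes from edgeR unless another tool is named. For miRNAs, 1 model over all 15 libraries gave each time point against 72 h PE, the steps between successive time points and a test over the 5 time points. For CLIP-seq, 1 model per table compared 24 h PBM with 72 h PE, on peaks and on counts summed over the peaks of each gene or miRNA precursor. Peaks without a gene, among them those annotated only as repeats, stayed out of the gene table. Peaks without any annotation alone held 27.4% of the counts. Levels are TMM-normalized counts scaled to a common total (CPM) as mean ± SD. The reads counted are miRNA reads in the miRNA table and reads in genes in the CLIP gene table. Fold changes carry the standard error (SE) of their log2 value. The shares of CLIP counts by annotation class were compared with two-sided exact permutation tests, whose smallest p with 3 against 3 is 0.1. The log2 ratio of the minor to the major arm of 28 precursors, with 0.5 added to counts, was tested with limma 3.58.1.

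Lists of miRNAs and of gene names were written before the data were examined, as were the comparisons, tests and the first set of alternative settings. The miRNA lists were ovary and embryo, midgut, muscle, neural, the let-7 complex, the miR-277, miR-275, miR-2, miR-9c and miR-12 clusters, metabolism-linked miRNAs, and miRNAs with known blood-meal or fat body roles. The gene lists were yolk protein precursors and lipid carriers, cytosolic ribosomal proteins, translation factors, mitochondrial energy, hormone pathway, insulin and TOR, lipid metabolism, carbohydrate metabolism, nutrient transport, immune genes, secretory pathway and chaperones, proteasome, hexamerins, muscle, gut digestion, ovary, cuticle and neural genes. Gene lists matched words in the names the CLIP table gives. Words were matched whole where a shorter match would take unrelated names, mitochondrial ribosomal proteins and kinases were left out of the ribosomal list, and miRNA precursors were left out of all gene lists. The CLIP gene lists share no tested gene. Among miRNA lists, the blood-meal list shares 3 members with the ovary list, 2 with the midgut list, 2 with the miR-275 cluster, 2 with the miR-277 cluster and 2 with the metabolism list, and the neural list shares 4 with the miR-9c cluster. Lists with at least 3 tested members were compared with all other items by limma's camera with a preset correlation of 0.01 and again with an estimated correlation. They were also tested by fry, which asks whether a list's members change and compares them with no other item.

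Named miRNAs are the 10 most abundant, up to 10 that rose and 10 that fell at each time point by size of the change, with an adjusted p under 0.05, a mean of at least 10 CPM and replicates that do not overlap, and members of the lists. Named CLIP genes are up to 12 in each direction with a name and at least 10 reads per library by the same rule, the 10 with the most reads, and list members past the threshold. Steps between successive time points for the miRNAs named there, and miR-92a-3p at 6 h, miR-1889-5p, miR-263a-5p and miR-276-5p at 24 h, miR-252-3p and miR-276-5p at 36 h and miR-316 at 48 h, were chosen after their values were seen, as were the ratios of single arms and precursors. The peak table does not name every gene, and 0 of its gene IDs matched the AaegL5 gene table at hand, so unnamed genes appear by ID only. Near-identical genes can share reads where the counting rule is not stated, as for the cathepsin b and ATP synthase beta genes, whose single values are uncertain for that reason.

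Total miRNA reads were 2112431 to 6317980 per library, so 3 counts, the most that a count of 0 leaves open, correspond to 0.475 to 1.42 CPM. CLIP-seq libraries held 69424 to 132758 counts in peaks, of which 3 counts correspond to 22.6 to 43.2 CPM. They held 48023 to 91360 counts in genes, so 3 counts correspond to a higher CPM in the gene table. Intervals for shares of a single library are 95% Wilson intervals from scipy 1.17.1. Intervals and floors cover counting error only. Replicate counts differed by far more than sampling noise, with chi-square per degree of freedom of 421 to 13241 in miRNA pairs and 2.37 to 7.56 in CLIP pairs, so every library was counted on its own. In the CLIP peaks, libraries with the same number deviated together (r of 0.386, 0.222 and 0.323 for numbers 1, 2 and 3), so by a rule set at 0.1 the numbers pair the CLIP peaks. The pairing comes from these correlations and not from the labels. With the pairing, 414 peaks passed (252 higher and 162 lower) in place of 365. In the CLIP gene table the correlations were 0.210, 0.070 and 0.157, so the rule did not pair it.

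These first settings were DESeq2's size factors, scaling by library totals, the DESeq2 1.42.0 test, and limma on log2 of the deposited RPM with 1 added. They also took in no filter, a filter of 10 CPM or of 10 reads in 3 libraries, a replicate block, only the compared time points in the model, the most abundant miRNA left out, peaks above the median count, a miRDeep2 score of at least 10 for predictions, and each library left out in turn. Added after seeing the data were the 3 most abundant CLIP genes left out, CDS and UTR peaks only, miRNA precursors scaled among themselves, rRNA peaks left out, and single libraries left out of the miRNA lists, the class shares and the mean miRNA shares. Each test across many items was tested on simulated data drawn from the real means, with 30 miRNAs or 200 CLIP items changed by known amounts. Of changes of 1 on the log2 scale, 50.0% (36 and 48 h) to 70.0% (6 h) were recovered in the comparisons with 72 h PE, 20.4% in CLIP peaks and 24.6% in CLIP genes. Of changes of 2, 86.7% were recovered in CLIP peaks and 93.5% in CLIP genes. A search of the peaks for miRNA seed matches needs the genome of this build and was not run. AGO1 CLIP-seq counts move with the level of a transcript as well as with AGO1 binding, and no messenger RNA levels of these samples are used here. Tables and tests used pandas 2.3.3 and Python 3.11.15, and plots matplotlib 3.10.9.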

Results

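Small RNA libraries of the mosquito fat body were compared at 72 h PE and at 6, 24, 36 and 48 h PBM, with 3 libraries at each time, to follow miRNAs through the cycle of yolk production that a blood meal starts. AGO1 CLIP-seq libraries from before (72 h PE) and after the blood meal (24 h PBM), with 3 at each time, were compared to find which RNAs AGO1 touched before and after the meal. The samples hold no unfed females of the later times. In every comparison with 72 h PE, the blood meal therefore cannot be told apart from the females' greater age. The small RNA libraries held 8558678 to 29670297 reads in total. Of these, miRNAs made up 22.1% ± 1.27 at 72 h PE, 23.0% ± 2.21 at 6 h, 23.5% ± 0.617 at 24 h, 23.6% ± 2.18 at 36 h and 23.5% ± 2.07 at 48 h PBM (SD, n = 3). The CLIP-seq libraries held 69424 to 132758 counts each. The p-values of single miRNAs, arm ratios, genes, peaks and class shares measure the spread between these libraries. The series' design text describes the libraries as independent biological replicates. Those of camera set list members against all other items, and those of the correlations between both assays permute miRNAs.

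A single miRNA, miR-8-3p, made up on average 52.8% of the miRNA reads, followed by miR-184 (7.85%), bantam-3p (6.64%), miR-317 (3.1%), miR-11-3p (2.99%), miR-14 (2.95%), miR-276-3p (2.83%), miR-2940-3p (2.68%), miR-281-5p (2.54%) and miR-8-5p (1.76%). The mean of miR-281-5p rests on 48 h PBM replicate 3, without which it was 1.20%, below miR-8-5p. The miR-8 family is conserved among insects and acts in growth and secretion in the fat body, and bantam promotes growth. The share of miR-8-3p lay between 36.3% in 48 h PBM replicate 3 (Wilson interval 36.3 to 36.4) and 61.8% in 72 h PE replicate 1 (61.7 to 61.8). It averaged 56.0% ± 5.02, 55.3% ± 2.22, 55.7% ± 0.642, 50.7% ± 5.47 and 46.5% ± 9.04 over the 5 times in order (n = 3 each). The low value at 48 h PBM coincided with 1 library in which miR-281-5p, a miRNA abundant in the mosquito midgut, took 21.3% of the miRNA reads (1343467 of 6317980; Wilson interval 21.2 to 21.3), against 3.54% or less in every other library.

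Of the 124 miRNAs, 114 had enough reads to be tested, and 54 of them varied over the 5 times by edgeR's quasi-likelihood F test after Benjamini-Hochberg adjustment. The means of 18 of the 54 spanned more than 4-fold, and those of 19 spanned less than 2-fold. Among the 54, the highest mean fell at 72 h PE for 10, at 6 h for 9, at 24 h for 14, at 36 h for 10 and at 48 h for 11, and 19 had their lowest mean at 6 h PBM. Against 72 h PE, 10 miRNAs rose and 4 fell at 6 h PBM, 20 rose and 7 fell at 24 h, 17 rose and 13 fell at 36 h, and 17 rose and 11 fell at 48 h. The split at 6 h was 14 and 7 with DESeq2, 10 and 7 with the replicate block, 10 and 6 with the 10 CPM filter, 9 and 6 with no filter, and 6 and 4 without 72 h PE replicate 1. The counts at an unadjusted p under 0.05 were 27, 36, 44 and 44. Replicates of both times did not overlap for 35, 54, 46 and 47 of the 114 miRNAs, where chance alone gives 10%.

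**Figure D1:**
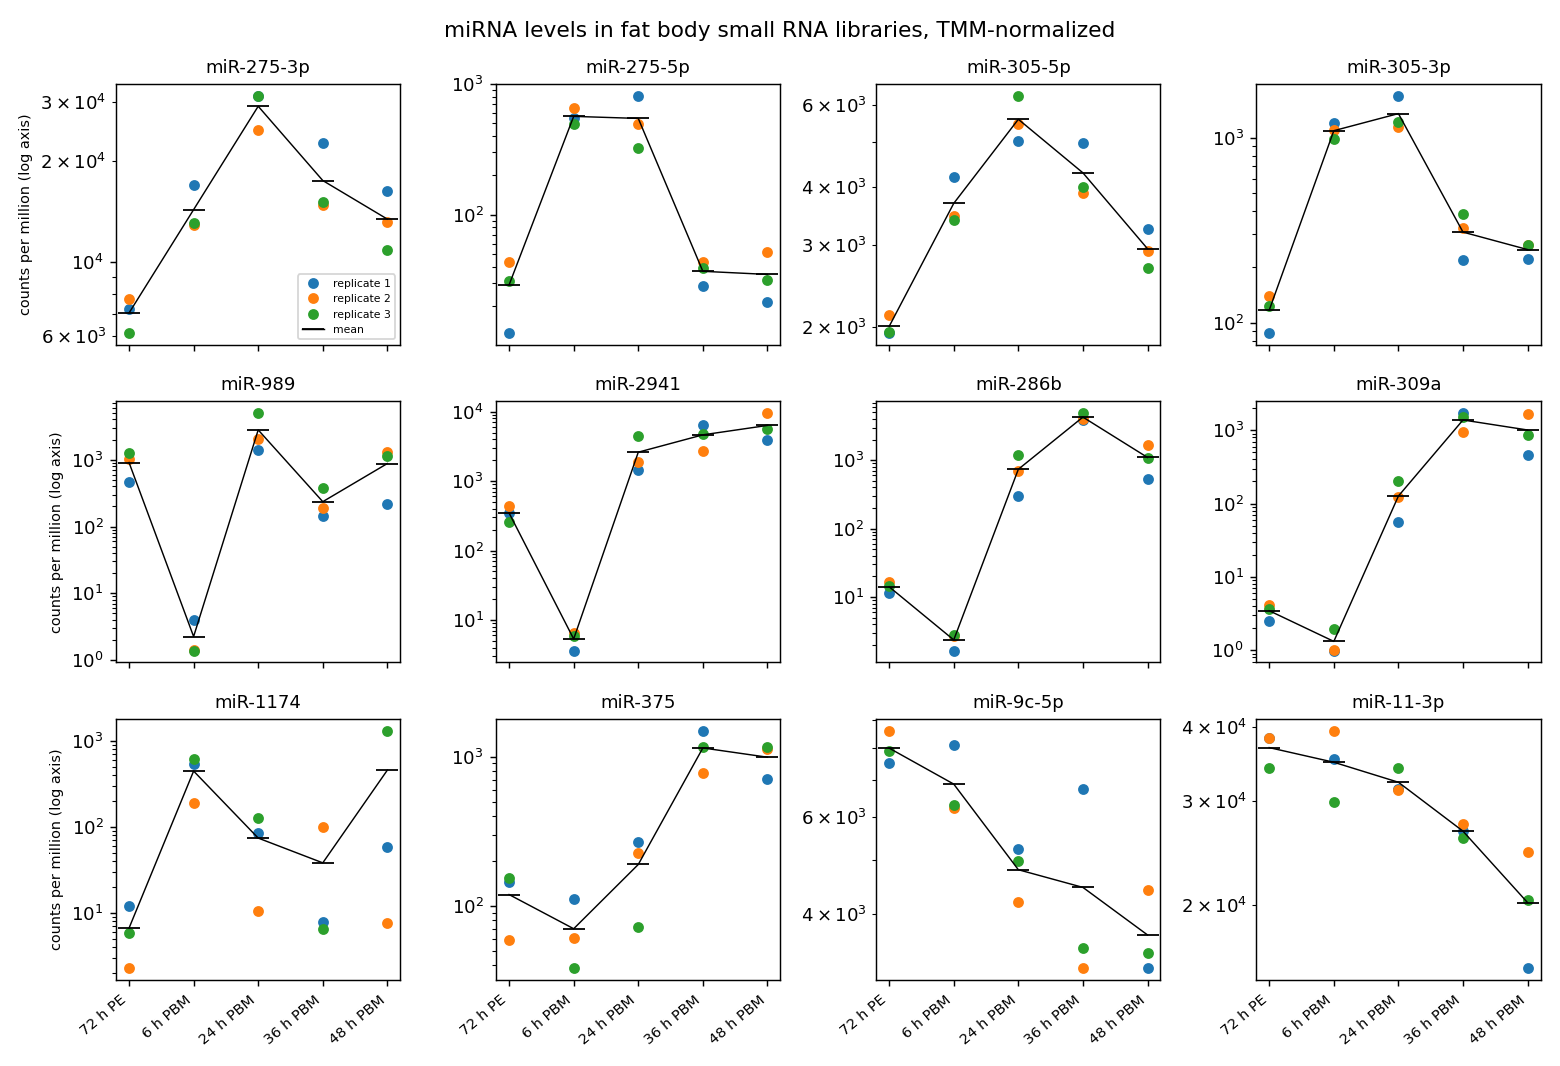
CPM (TMM-normalized counts, log axis) of 12 miRNAs at 72 h PE and 6, 24, 36 and 48 h PBM, with a point for each of the 3 libraries at a time, coloured by replicate number, and the line and bar at the mean. Both arms of miR-275 and miR-305 are higher at 6 and 24 h PBM than at 72 h PE, miR-989 is lowest at 6 h PBM (2.26 on average), and miR-286b and miR-309a are highest at 36 h PBM (4282 and 1380).

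The comparison of 6 h PBM with 72 h PE addresses the first hours after the blood meal. At 6 h PBM, both arms of miR-275 and of miR-305, which lie close together in the genome and are made together, were higher, and 4 miRNAs known from the ovary and the embryo were far lower. miR-275-3p, which is needed for blood digestion and egg development in this mosquito, rose 2.04-fold from 7027 ± 815 to 14314 ± 2336 CPM (SD, n = 3 each; log2 change 1.03, SE 0.21, adjusted p = 0.00404). Its opposite arm miR-275-5p rose 19.5-fold from 28.9 ± 15.7 to 564 ± 83.3 CPM (SE 0.51, adjusted p = 3.40e-05). miR-305-3p rose 9.34-fold to 1092 ± 108 CPM (SE 0.27, adjusted p = 2.83e-06), and miR-305-5p rose 1.84-fold to 3686 ± 437 CPM (SE 0.14, adjusted p = 0.000741). miR-8-5p, the minor arm of the miR-8 precursor, rose 1.77-fold to 20577 ± 1321 CPM (adjusted p = 0.00325), while miR-8-3p was not called.

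The fallen miRNAs at 6 h PBM were miR-989, miR-2941, miR-2946 and miR-286b. miR-989, which is abundant in mosquito ovaries, fell from 908 ± 395 to 2.26 ± 1.47 CPM, with 5 to 12 reads left per library (log2 change −8.69, SE 0.95, adjusted p = 2.30e-05). miR-2941 fell from 347 ± 88.9 to 5.33 ± 1.52 CPM (log2 change −6.0, SE 0.57, adjusted p = 7.48e-06), and miR-2946 fell from 68.1 ± 12.9 to 1.40 ± 0.970 CPM (log2 change −5.54, SE 0.65). miR-286b, a member of a family made in the early embryo, fell from 14.1 ± 2.76 to 2.36 ± 0.620 CPM (log2 change −2.55, SE 0.54, adjusted p = 0.00527), a call lost with limma on the deposited RPM (adjusted p = 0.0690). miR-92a-3p averaged 762 ± 696 CPM against 51.7 ± 4.23 and was called (adjusted p = 0.00475). However, 6 h PBM replicate 2 held 48.3 CPM, within the 72 h PE values, and the call was lost with only both compared times in the model (adjusted p = 0.0613).

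The remaining risers at 6 h PBM were less firm. miR-7 (log2 change 1.85, SE 0.53, adjusted p = 0.0376), miR-278-5p (1.01, SE 0.25, adjusted p = 0.0122), miR-276-5p (0.67, SE 0.16, adjusted p = 0.0122) and miR-12-3p (0.68, SE 0.20, adjusted p = 0.0420) lost their calls without single libraries. For miR-7 these were 72 h PE replicate 1 or 2 or 6 h PBM replicate 2 or 3 (adjusted p of 0.0855 to 0.170), and for miR-278-5p 72 h PE replicate 1 or 2 or 6 h PBM replicate 2 (0.0529 to 0.0650). For miR-276-5p they were replicate 1 of either time (0.0801 and 0.0980), and for miR-12-3p 72 h PE replicate 1 or 2 or any 6 h PBM library (0.0620 to 0.173). miR-7 was also lost with only both compared times in the model (0.0613), and miR-12-3p with no filter (0.0748).

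At 24 h PBM, near the peak of yolk production, the miR-275 and miR-305 arms stayed above 72 h PE, and miR-286b, miR-2941 and miR-2946, which were low at 6 h, stood above their 72 h PE level. miR-989, also low at 6 h, was not called (log2 change 1.62, adjusted p = 0.113). miR-275-3p rose 4.15-fold to 29161 ± 3746 CPM (log2 change 2.05, SE 0.21, adjusted p = 7.92e-06, n = 3), miR-275-5p 18.8-fold to 544 ± 250 CPM, miR-305-3p 11.6-fold to 1352 ± 298 CPM and miR-305-5p 2.78-fold to 5582 ± 641 CPM. miR-286b rose 52.2-fold to 739 ± 459 CPM (log2 change 5.71, SE 0.55, adjusted p = 6.79e-06). miR-309b-3p rose 41.5-fold to 108 ± 66.3 CPM and miR-309a 36.3-fold to 127 ± 73.9 CPM (log2 change 5.18, SE 0.60, adjusted p = 2.28e-05). miR-309 is known to rise in mosquito ovaries after a blood meal and to act there in follicle growth. miR-2944b-5p rose from 0.591 ± 0.345 CPM, which is near the floor, to 36.6 ± 10.5 CPM (log2 change 5.88, SE 0.60), miR-2941 rose 7.51-fold to 2606 ± 1630 CPM and miR-2946 5.29-fold to 361 ± 219 CPM.

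Outside these groups, miR-263a-3p (log2 change 1.74, SE 0.36, adjusted p = 0.00311), miR-1 (1.68, SE 0.39, adjusted p = 0.00669), a miRNA of muscle, and miR-276-5p (1.38, SE 0.16) rose at 24 h PBM. miR-34-5p rose 2.12-fold to 6769 ± 1778 CPM (adjusted p = 0.00518), miR-71-5p 2.04-fold (adjusted p = 0.0114) and miR-276-3p 1.47-fold to 35228 ± 2611 CPM. The call of miR-276-3p (adjusted p = 0.00270) was lost with only both compared times in the model (0.0513). miR-278-5p fell from 592 ± 24.5 to 257 ± 64.1 CPM (log2 change −1.21, SE 0.25, adjusted p = 0.00311) and miR-11-5p from 6708 ± 787 to 3726 ± 934 CPM (log2 change −0.85, SE 0.21, adjusted p = 0.0101). Library totals gave 22 higher and 4 lower miRNAs at 24 h PBM, and limma on the deposited RPM 22 and 2, against 20 and 7 with TMM. With no filter there were 20 and 13, with the 10 CPM filter 21 and 12, with DESeq2 23 and 12, and with only both compared times in the model 19 and 11. Without any single library but 72 h PE replicate 3, 16 to 19 were higher and 2 to 4 lower.

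Several calls at 24 h PBM were lost without single libraries, and some of these with another scaling as well. miR-7 (log2 change 1.59, adjusted p = 0.0454) and miR-306-3p (−1.72, adjusted p 0.0348) were lost without 72 h PE replicate 1 or 2 or any 24 h PBM library, with adjusted p of up to 0.154 for both. miR-988-3p (−0.99, adjusted p 0.0182) was lost without 72 h PE replicate 1 or 2 or 24 h PBM replicate 2 or 3 (0.0686 to 0.0758), and miR-277-5p (1.52, adjusted p 0.0150) without 72 h PE replicate 1 or 2 or 24 h PBM replicate 1 (0.0510 to 0.0745). miR-9c-5p (−0.74, adjusted p 0.0497) was lost without any of the 6 libraries (0.0819 to 0.160). miR-1889-5p (1.5, adjusted p 0.0136) was lost without 72 h PE replicate 1 (0.0692), and miR-308-5p (−0.59, adjusted p 0.0131) without 72 h PE replicate 1 or 24 h PBM replicate 2 (0.0692 and 0.0725). The call of miR-263a-5p (1.01, adjusted p 0.0349) was lost without 72 h PE replicate 1 or 24 h PBM replicate 3 (0.139 and 0.142), and iab-4-5p (−0.77, adjusted p 0.0136) without 24 h PBM replicate 1 or 2 (0.0510 and 0.0543). The falls of miR-306-3p, miR-988-3p and miR-9c-5p were also lost with library totals (0.0511, 0.0511 and 0.113) and with limma on the deposited RPM (0.0903, 0.0657 and 0.161). Those of miR-308-5p and iab-4-5p were lost with limma (0.0657 and 0.104), and the rise of miR-263a-5p with only both compared times in the model (0.0694).

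At 36 h PBM, when yolk production is declining, 8 of the 13 tested ovary and embryo miRNAs were higher than at 72 h PE and miR-989 was lower, and 5 of the 8 miR-9c cluster members were lower. miR-286b reached 4282 ± 524 CPM against 14.1 ± 2.76 at 72 h PE (log2 change 8.24, SE 0.61, adjusted p = 4.38e-07, n = 3). miR-309a reached 1380 ± 397 CPM, 395-fold higher (log2 change 8.63, SE 0.69), miR-309b-3p 1095 ± 314 CPM, 420-fold higher, and miR-2944b-5p 337 ± 147 CPM (log2 change 9.09, SE 0.66). miR-2941 rose 13.4-fold to 4632 ± 1818 CPM, miR-2944b-3p 13.0-fold to 46.2 ± 25.3 CPM and miR-2946 9.81-fold to 669 ± 193 CPM. miR-375, a midgut-enriched miRNA that also rises in mosquitoes after blood feeding, rose 9.62-fold from 119 ± 51.8 to 1144 ± 358 CPM (log2 change 3.27, SE 0.56, adjusted p = 0.000640). miR-317 rose 2.89-fold from 21926 ± 8097 to 63261 ± 12201 CPM (adjusted p = 0.00779) and miR-1889-5p 5.60-fold to 746 ± 336 CPM.

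Of the miR-275 and miR-305 arms, 3 of 4 were called higher at 36 h PBM. miR-275-3p was still 2.49-fold above 72 h PE at 17486 ± 4480 CPM (adjusted p = 0.000435), whereas miR-275-5p, at 36.8 ± 7.50 CPM, was not called. miR-8-5p rose by 0.81 on the log2 scale (SE 0.16, adjusted p = 0.00179). Of the fallen miRNAs, miR-988-3p (log2 change −1.32, SE 0.28, adjusted p = 0.00295), miR-278-5p (−1.23, SE 0.25, adjusted p 0.00202), miR-9b (−0.94, SE 0.20, adjusted p 0.00315) and miR-308-5p (−0.90, SE 0.15, adjusted p 0.000640) kept their calls in every alternative tried. Library totals gave 22 higher and 5 lower miRNAs and limma on the deposited RPM 24 and 4, against 17 and 13 with TMM. The balance moved the other way without 36 h PBM replicate 2 (15 higher and 22 lower), with the 10 CPM filter (16 and 17) and with no filter (17 and 17). It was 23 and 21 with the replicate block, and 17 and 5 or 19 and 7 without 72 h PE replicate 2 or 3.

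Several other calls at 36 h PBM were lost without single libraries or with another scaling. miR-989 averaged 235 ± 121 CPM against 908 ± 395 (log2 change −1.95, SE 0.67, adjusted p = 0.0499), and was lost without 72 h PE replicate 2 or 3 or 36 h PBM replicate 1 or 2 (0.0605 to 0.158). miR-9c-5p (−0.84, adjusted p 0.0250) was lost without 72 h PE replicate 2 or 3 or 36 h PBM replicate 3 (0.0640 to 0.110), and changed by −1.27 without 36 h PBM replicate 1. miR-9c-3p (−0.84, adjusted p 0.0216) was lost without 72 h PE replicate 2 or 36 h PBM replicate 3 (0.0882 and 0.0761), and miR-306-5p (−0.46, adjusted p 0.0250) without any 72 h PE library or 36 h PBM replicate 3 (0.0644 to 0.0843). miR-306-3p (−1.77, adjusted p 0.0278) was lost without 72 h PE replicate 1 or 2 or 36 h PBM replicate 1 or 3 (0.0515 to 0.110). miR-276-3p (0.38, adjusted p 0.0219) was lost without 72 h PE replicate 1 or 36 h PBM replicate 1 or 2 (0.0637 to 0.380), and miR-276-5p (0.81, adjusted p 0.00202) without 36 h PBM replicate 2 (0.0501). The falls of miR-989, miR-9c-5p, miR-9c-3p, miR-306-5p and miR-306-3p, the last 4 being members of the miR-9c cluster, were also lost with library totals (0.0550 to 0.155) and with limma on the deposited RPM (0.0692 to 0.292). With only both compared times in the model, miR-9c-5p, miR-276-3p and miR-306-5p were lost (0.110, 0.110 and 0.0881), and with no filter miR-276-3p (0.0892).

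At 48 h PBM, 8 of the 13 tested ovary and embryo miRNAs were higher than at 72 h PE and 5 were not called, among them miR-989 (log2 change −0.05, adjusted p = 0.941). Of the 8, miR-2944b-3p was lost without 72 h PE replicate 2 or 3 or 48 h PBM replicate 2 (0.0901, 0.0536 and 0.0915). The abundant miR-8-3p, miR-11-3p and miR-9c-5p were lower than at 72 h PE. miR-309a stood at 1008 ± 625 CPM, 289-fold above 72 h PE (log2 change 8.17, SE 0.68, adjusted p = 1.52e-06, n = 3), miR-309b-3p was 297-fold higher, miR-286b 77.7-fold higher at 1100 ± 572 CPM, miR-2941 18.2-fold higher at 6328 ± 2876 CPM and miR-2946 13.6-fold higher. miR-375 was 8.34-fold higher at 992 ± 250 CPM (adjusted p = 0.00162), miR-275-3p 1.91-fold higher at 13406 ± 2694 CPM (0.00557) and miR-305-3p 2.13-fold higher (0.00557). miR-9c-5p fell from 8006 ± 555 to 3659 ± 657 CPM (log2 change −1.13, SE 0.25, adjusted p = 0.00557), miR-9c-3p likewise by −1.13 (SE 0.24, adjusted p 0.00457) and miR-9b by −0.99 (SE 0.20, adjusted p 0.00345). miR-11-3p fell from 36871 ± 2423 to 20189 ± 4461 CPM (log2 change −0.87, SE 0.16, adjusted p = 0.00162).

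Some falls at 48 h PBM depended on the scaling. miR-8-3p fell from 619530 ± 63769 to 417100 ± 68044 CPM (log2 change −0.57, SE 0.13, adjusted p = 0.00582), a call lost with library totals (0.143) and with limma on the deposited RPM (0.405). miR-279 (−0.79, adjusted p 0.00557) and miR-308-5p (−0.62, adjusted p 0.00928) were lost with the same scalings (0.102 and 0.123 with totals, 0.111 and 0.216 with limma), and miR-306-5p (−0.75, adjusted p 0.00177) with limma (0.0566). miR-988-3p (−1.09, adjusted p 0.0105) and miR-125-5p (−0.74, adjusted p 0.0274) were lost with library totals (0.0686 and 0.103) and with limma (0.0582 and 0.216). Library totals gave 33 higher and 5 lower miRNAs, and limma on the deposited RPM 29 and 4, against 17 and 11 with TMM. Falls outnumbered rises with the replicate block (19 higher and 23 lower), with no filter (15 and 21), without 48 h PBM replicate 1 (17 and 18) and with only both compared times in the model (13 and 14), and DESeq2 gave 20 and 17. The median log2 change of all miRNAs at 48 h PBM was 0.34 by library totals and 0.35 with limma on the deposited RPM, against 0.04 by TMM.

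The midgut miRNAs miR-1174, miR-1175-3p and miR-1175-5p were called higher at 48 h PBM (log2 changes of 6.10, 5.84 and 6.67; SE 1.91, 1.85 and 2.02, adjusted p = 0.0369, 0.0369 and 0.0317). In 48 h PBM replicate 3, miR-1174 made up 0.138% of the miRNA reads. Without that library, the log2 changes were 2.29, 2.15 and 3.28 (adjusted p = 0.261, 0.297 and 0.180). The calls were also lost without any single 72 h PE library (0.0804 to 0.125), with limma on the deposited RPM (0.0717 to 0.0978), with the replicate block (0.0680 to 0.0926) and with only both compared times in the model (0.0794 to 0.122). At 6 h PBM, miR-1174 averaged 446 ± 225 CPM against 6.67 ± 4.90 at 72 h PE, which was not called. Among other calls at 48 h PBM, miR-305-5p (0.55, adjusted p 0.0105) was lost without 48 h PBM replicate 1 (0.0757) and with no filter (0.0676). The call of miR-988-3p was lost without 72 h PE replicate 2 (0.0507), and that of miR-125-5p without 72 h PE replicate 2 or 3 or 48 h PBM replicate 3 (0.104, 0.0934 and 0.0572).

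Successive times were compared to find when the miRNAs moved. From 6 to 24 h PBM 13 miRNAs rose and 4 fell, and from 24 to 36 h PBM 11 rose and 9 fell. From 36 to 48 h PBM edgeR called 0, with 24 at an unadjusted p under 0.05, while DESeq2 called 15 and limma on the deposited RPM 7. Replicates did not overlap for 38, 42 and 22 of the 114 miRNAs in the 3 steps, where chance gives 10%. miR-989 rose by 10.31 on the log2 scale from 6 to 24 h PBM (SE 1.0, adjusted p = 3.74e-06), from 2.26 to 2794 ± 1914 CPM, and fell by 3.57 from 24 to 36 h PBM (SE 0.72, adjusted p = 0.00365). miR-275-5p fell by 3.88 (SE 0.50, adjusted p = 0.000200) and miR-305-3p by 2.13 (SE 0.25, adjusted p 0.000185) from 24 to 36 h PBM. miR-309a rose by 3.45 (SE 0.54, adjusted p 0.000718), miR-375 by 2.59 (SE 0.55, adjusted p 0.00463) and miR-286b by 2.53 (SE 0.47, adjusted p 0.00225) in the same step. From 6 to 24 h PBM, more fell with DESeq2's size factors (13 higher and 7 lower), with the DESeq2 test (16 and 10), with miR-8-3p left out (13 and 8) and without 24 h PBM replicate 3 (14 and 7). Fewer fell with only both compared times in the model (12 and 1) and without 24 h PBM replicate 1 or 2 (13 and 2, 14 and 2). From 24 to 36 h PBM, library totals gave 11 and 5, only both compared times in the model 11 and 3, and leaving out 24 h PBM replicate 1 or 3 gave 9 and 5 or 12 and 4, whereas falls outnumbered rises with the replicate block (14 higher and 18 lower) and without 36 h PBM replicate 2 (9 and 15).

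The opposite arms of 28 precursors were compared within libraries. The share of miR-275 reads from its minor 5p arm was 0.411% at 72 h PE, 3.86% at 6 h, 1.84% at 24 h, 0.224% at 36 h and 0.270% at 48 h PBM, and that of miR-305 from its 3p arm was 5.48%, 22.9%, 19.6%, 6.89% and 7.85%. The log2 ratio of minor to major arm rose by 3.43 for miR-275 (SE 0.53; limma adjusted p = 0.000310, n = 3) and by 2.37 for miR-305 (SE 0.31, adjusted p 0.000104) at 6 h PBM. It fell by 3.04 and 1.76 from 24 to 36 h PBM (adjusted p = 0.00108 for both). The 5p arm of miR-278, a miRNA of insulin signalling and energy balance in flies, took 45.0% of its reads at 72 h PE, 65.1% at 6 h and 24.2% at 24 h PBM. The log2 ratio fell by 2.57 from 6 to 24 h (adjusted p = 5.75e-06). For miR-2944b the 3p arm held 85.8% at 72 h PE, with 14 to 17 reads against 1 to 4 of the 5p arm, and 10.4% at 24 h PBM, with 9 to 31 against 118 to 165 (limma adjusted p = 5.83e-06 for the ratio). At 6 h PBM both arms were low, with 5 to 11 and 0 to 2 reads. In the comparisons with 72 h PE, the ratio rose for 6 and fell for 2 precursors at 6 h, 6 and 5 at 24 h, 2 and 3 at 36 h, and 1 and 1 at 48 h PBM.

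The ovary and embryo list had 13 tested members of 16. At 6 h 0 rose and 4 fell, at 24 h 6 rose and 0 fell, at 36 h 8 rose and 1 (miR-989) fell, and at 48 h 8 rose and 0 fell, with the same counts when adjusted over the list alone. Its median log2 changes were −1.07, 1.62, 3.29 and 2.42 at the 4 times. Against all other miRNAs the list stood lower at 6 h (camera adjusted p = 0.000113) and higher at 24 h (0.00290), 36 h (3.02e-06) and 48 h (4.89e-06), calls that were lost at all 4 times (adjusted p = 0.168, 0.300, 0.124 and 0.124 with an estimated correlation). By fry the ovary and embryo list was called at all 4 times (adjusted p = 0.00211, 0.00147, 0.000113 and 0.000289). All 4 members of the miR-275 cluster rose at 6 and 24 h, and 3 at 36 and 48 h PBM. The cluster stood higher than other miRNAs at 6 h (adjusted p = 1.18e-07) and 24 h (2.01e-07), which held at both times (adjusted p = 0.00196 with an estimated correlation). At 36 h its call (0.0361) was lost with an estimated correlation (adjusted p = 0.124 with an estimated correlation), with no filter (0.0757), with the 10 CPM filter (0.0593), with DESeq2 (0.0978), and without 72 h PE replicate 1, 36 h PBM replicate 2 or 48 h PBM replicate 2 (0.0693, 0.129 and 0.119). It was not called at 48 h (0.176). Adjusted over the list alone the counts for this cluster were the same. By fry the cluster was called at all 4 times (adjusted p of 9.74e-08 to 0.000456).

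Of the 8 members of the miR-9c cluster 0, 2, 5 and 4 fell at the 4 times and 0 rose (6 fell at 36 h when adjusted over the list alone). By camera the list stood lower at 36 h (adjusted p = 0.0102) and 48 h (0.00547), lost at both times (adjusted p = 0.168 and 0.124 with an estimated correlation), and was not called at 6 h (0.749) and 24 h (0.176). By fry it was called at 24, 36 and 48 h (adjusted p = 0.0283, 0.000348 and 0.000255) and not at 6 h (0.240). Of the 14 tested members of 15 with known blood-meal or fat body roles, 3, 5, 5 and 6 rose and 0, 0, 0 and 1 fell; adjusted over the list alone, 4 rose and 1 fell at 6 h and 6 rose at 24 h. The member that fell is miR-8-3p. This list stood higher at 24 h (adjusted p = 0.0178), 36 h (0.0305) and 48 h (0.0333), lost at these times (adjusted p = 0.124 with an estimated correlation), and was not called at 6 h (0.238), where its median (−0.04) and mean (0.71) differ in sign. With limma on the deposited RPM its adjusted p was 0.0687 at 36 h and 0.0725 at 48 h, and without 48 h PBM replicate 1 it was 0.0588 at 48 h. By fry this list was called at all 4 times (adjusted p = 0.000646, 2.00e-07, 2.00e-07 and 5.11e-07). The midgut list had 6 members, of which 0, 0, 1 and 4 rose (3 rose at 6 h when adjusted over the list alone), and was not called at any time (0.281, 0.763, 0.634 and 0.189).

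The AGO1 CLIP-seq table holds 100836 peaks with 575708 counts. The median peak was 21 bases long (range 1 to 702), and 56.2% of the peaks had a single count. Coding sequence (CDS) took 23.3% ± 3.25 of the counts at 72 h PE and 28.8% ± 2.15 at 24 h PBM (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). Introns took 7.52% ± 0.799 and 5.23% ± 0.664 (exact p = 0.1). As a share of peaks in place of counts both went the other way, CDS from 31.0% to 27.1% and introns from 9.53% to 10.2% (exact p = 0.2 for both). By counts, 3′ UTRs, where miRNA sites usually lie, took 5.51% ± 0.643 and 4.17% ± 0.411 (exact p = 0.1). miRNA precursors took 21.2% ± 4.04 and 23.8% ± 2.23 (exact p = 0.4) and 5′ UTRs 1.86% ± 0.303 and 1.61% ± 0.206 (exact p = 0.3). Over the 24 classes no difference passed after adjustment (the lowest adjusted p was 0.343). The CDS difference of 5.52 percentage points was 3.65 without 72 h PE replicate 1, and the precursor difference of 2.55 was 0.725 without 72 h PE replicate 2 and 4.72 without 72 h PE replicate 1.

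At 24 h PBM, AGO1 CLIP-seq reads on genes of yolk production were 7.63-fold to 58.1-fold higher than at 72 h PE, and reads on uricase, allantoinase and fatty acid synthase were lower. Reads on vitellogenin-A1 (AAEL010434), the main yolk protein precursor, rose 41.1-fold from 1080 ± 638 to 44245 ± 13949 CPM (SD, n = 3 each; log2 change 5.36, SE 0.43, adjusted p = 2.81e-09). Vitellogenic carboxypeptidase (AAEL006563), a protease stored in yolk, rose 43.3-fold from 208 ± 112 to 8870 ± 1832 CPM (SE 0.41, adjusted p = 2.01e-10). Reads on 5 cathepsin b genes rose, among them AAEL007599 58.1-fold (SE 0.54, adjusted p 4.38e-08), AAEL012216 45.8-fold (SE 0.44, adjusted p 5.82e-10), AAEL015312 34.9-fold (SE 0.42, adjusted p 5.97e-10) and AAEL009642 33.9-fold higher (SE 0.52, adjusted p 4.72e-08). The genes with the most reads were unnamed, AAEL006138 with 0.325% of the counts at 72 h PE and 7.11% at 24 h PBM (log2 change 5.11, SE 0.37) and AAEL006126 with 0.166% and 4.93% (5.56, SE 0.38).

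**Figure D2:**
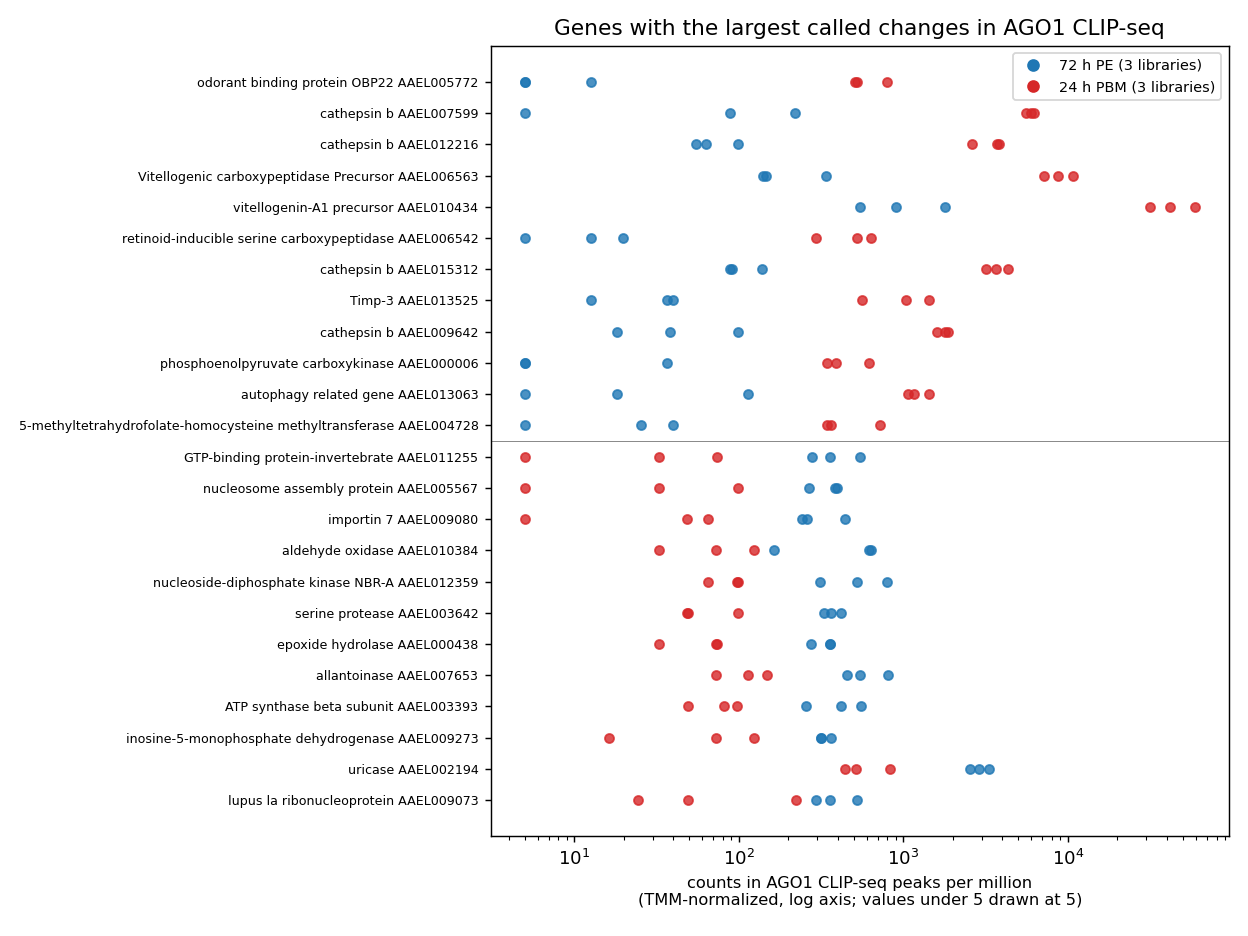
CPM in AGO1 CLIP-seq peaks (TMM-normalized counts, log axis, values under 5 drawn at 5) for the 12 named genes that rose most and the 12 that fell most, with a point for each of the 3 libraries at 72 h PE (blue) and at 24 h PBM (red). Vitellogenin-A1 lies at 1080 on average at 72 h PE and 44245 at 24 h PBM, and uricase at 2910 and 596.

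Other named genes that rose were odorant binding protein OBP22 (AAEL005772), with 1 count at 72 h PE and 85 at 24 h PBM, a ratio of 121 after scaling (exact counting interval 21.1 to 4819, adjusted p = 1.54e-06). Phosphoenolpyruvate carboxykinase (AAEL000006), the key enzyme of gluconeogenesis, had 2 and 62 counts, a ratio of 44.0 (interval 11.7 to 371, adjusted p = 2.71e-05), and a retinoid-inducible serine carboxypeptidase (AAEL006542) had 2 and 70, a ratio of 49.7 (13.2 to 418, adjusted p 9.52e-06). Timp-3 (AAEL013525), an inhibitor of matrix proteases, rose 34.1-fold (SE 0.61, adjusted p 6.94e-07), with 90.5% of its reads in introns, and an autophagy related gene (AAEL013063) 22.7-fold (SE 0.61, adjusted p 5.95e-06), with 53.6% in introns. A 5-methyltetrahydrofolate-homocysteine methyltransferase (AAEL004728) rose 19.6-fold (SE 0.70, adjusted p 4.86e-05). The nuclear receptor E75 (AAEL007397), an early gene of the ecdysone response, rose 4.83-fold from 121 ± 6.89 to 588 ± 126 CPM (SE 0.50, adjusted p 0.00139). Prophenoloxidase (AAEL013492), an enzyme of melanization, rose 7.79-fold (log2 change 2.96, SE 0.60, adjusted p 0.000714), or by 4.51 on the log2 scale without 72 h PE replicate 1. E74 (AAEL000741), another early ecdysone gene, rose by 3.09 (SE 0.69, adjusted p 0.00154), with 69.4% of its reads in introns, a call lost without 72 h PE replicate 2 (0.0506) or 24 h PBM replicate 3 (0.0599).

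Of the genes that fell, uricase (AAEL002194) and allantoinase (AAEL007653), successive enzymes of uric acid breakdown, fell from 2910 ± 400 to 596 ± 204 CPM (log2 change −2.30, SE 0.36, adjusted p = 2.71e-05) and from 603 ± 181 to 112 ± 37.7 CPM (log2 change −2.40, SE 0.53, adjusted p 0.00126). A GTP-binding protein (AAEL011255, log2 change −3.40, SE 0.69, adjusted p 0.000587), a nucleosome assembly protein (AAEL005567, −2.96, SE 0.68, adjusted p 0.00196) and importin 7 (AAEL009080, −2.85, SE 0.67, adjusted p 0.00236), which carries proteins into the nucleus, fell most. Aldehyde oxidase (AAEL010384, −2.68, adjusted p 0.00313), a nucleoside-diphosphate kinase (AAEL012359, −2.63, adjusted p 0.00126), a serine protease (AAEL003642, −2.49, adjusted p 0.00210) and an epoxide hydrolase (AAEL000438, −2.48, adjusted p 0.00274) fell as well. Fatty acid synthase (AAEL001194) fell from 11877 ± 3723 to 5137 ± 279 CPM (log2 change −1.21, SE 0.30, adjusted p 0.00431), lost without 72 h PE replicate 3 (0.0531). IMP dehydrogenase (AAEL009273, −2.31, adjusted p 0.00666), an enzyme of guanine nucleotide synthesis, was lost with no filter (0.0537). The lupus La protein (AAEL009073, −2.04, adjusted p 0.0164) was lost without 24 h PBM replicate 1 or 3 or 72 h PE replicate 2 or 3 (0.0624 to 0.0947) and with no filter (0.0604), and changed by −3.25 without 24 h PBM replicate 2.

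In all, 687 genes and precursors were tested, of which 91 rose and 79 fell (258 at an unadjusted p under 0.05). Replicates did not overlap for 41.6% of the 687, where chance gives 10%. By library totals 55 rose and 239 fell, and the median log2 change was −0.75 in place of 0.07. Both scalings called the same 134 genes and precursors. The 7 named calls that library totals lost were all rises. The smaller rises by TMM and the additional falls by library totals therefore depend on the scaling. With no filter 95 rose and 37 fell, with DESeq2 85 and 61, and without 72 h PE replicate 2 or 3 78 and 47 or 90 and 40.

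All 7 tested members of the yolk protein precursor and lipid carrier list (12 measured) rose, also when adjusted over the list alone. Their median log2 change was 5.36 (camera adjusted p = 2.39e-20), and the call held (adjusted p = 0.0177 with an estimated correlation). The 7 are vitellogenin-A1, vitellogenic carboxypeptidase and 5 cathepsin b genes, so no lipid carrier was tested. The cathepsin b genes can share reads, so these members may not be separate. The smallest rise among the 7 was 7.63-fold, for cathepsin b AAEL009637 (SE 0.34, adjusted p 3.18e-07). Beside these, vitelline membrane protein 15a-1 (AAEL013027), an eggshell protein made in the ovary, had 0, 1 and 2 counts at 72 h PE and 8, 26 and 185 at 24 h PBM, and was picked after its counts were seen. Of 61 tested cytosolic ribosomal proteins (86 measured), 0 rose and 5 fell (0 when adjusted over the list alone), with a median of −0.54. The list stood lower (adjusted p = 0.000281), a call lost (adjusted p = 0.239 with an estimated correlation). The 5 are S2 (AAEL010168, log2 change −1.10, SE 0.32, adjusted p 0.0122), P0 (AAEL010821, −1.18, adjusted p 0.0173), L17 (AAEL011471, −1.04, adjusted p 0.0370), L44/L41 (AAEL003942, −1.43, adjusted p 0.0430) and L10a (AAEL013221, −1.19, adjusted p 0.0439), and each call was lost without at least 1 library. S2 was lost without 24 h PBM replicate 2 or 72 h PE replicate 3 (0.0642 and 0.0722). P0 was lost without 72 h PE replicate 2 or 3 or 24 h PBM replicate 2 or 3 (0.0546 to 0.107), and L17 and L44/L41 without any library but 24 h PBM replicate 1 (0.0534 to 0.188). L10a was lost without any but 72 h PE replicate 1 (0.0693 to 0.107). All 5 were lost with no filter (0.0546 to 0.244). L44/L41 was also lost with DESeq2 (0.0517), L44/L41 and L10a with peaks above the median count (0.0624 and 0.0502), and L17 and L10a with CDS and UTR peaks only (0.0609 and 0.127).

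Of 9 tested translation factors (39 measured), 4 fell and 1 rose (7 and 1 when adjusted over the list alone), with a median of −1.34 (camera adjusted p = 0.0332). That call was lost with library totals (0.0503), without 24 h PBM replicate 2 or 3 (0.0824 and 0.0942), and with an estimated correlation (adjusted p = 0.239 with an estimated correlation). Elongation factor 1 gamma (AAEL011288) fell from 837 ± 239 to 245 ± 128 CPM (log2 change −1.79, SE 0.47, adjusted p 0.00610). The call of eIF3b (AAEL007718, −1.98, adjusted p 0.0106) was lost without 72 h PE replicate 1 (0.0893). That of eIF3a (AAEL007078, −1.63, adjusted p 0.0279) was lost without 24 h PBM replicate 1 or 3 or 72 h PE replicate 2 or 3 (0.0762 to 0.133). Elongation factor 1 beta, delta (AAEL009313, −1.53, adjusted p 0.0309) was lost without 72 h PE replicate 1 or 3 or 24 h PBM replicate 2 or 3 (0.0693 to 0.146). Both eIF3a and this factor were lost with no filter (0.246 and 0.166), and eIF3a with DESeq2 (0.0514) and with CDS and UTR peaks only (0.0512). The riser was 4EBP (AAEL001864, 1.41, SE 0.39, adjusted p 0.00963), which binds and blocks an initiation factor, and it was lost with library totals (0.158) and without 72 h PE replicate 2 or 3 (0.116 and 0.0675).

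All 4 tested mitochondrial energy genes (43 measured) fell, also when adjusted over the list alone, with a median of −1.75 (camera adjusted p = 0.0307), lost with library totals (0.0503) and with an estimated correlation (adjusted p = 0.239 with an estimated correlation). All 4 encode ATP synthase subunits. Subunit beta AAEL003393 fell by 2.38 on the log2 scale (SE 0.58, adjusted p = 0.00313). Subunit gamma (AAEL008848, −1.93, adjusted p 0.0261) was lost without any 72 h PE library or 24 h PBM replicate 3 (0.0621 to 0.143). Beta AAEL002827 (−1.57, adjusted p 0.0426) was lost without 72 h PE replicate 2 or 3 or 24 h PBM replicate 1 or 3 (0.0621 to 0.201). Alpha (AAEL012175, −1.53, adjusted p 0.0249), whose replicates overlap, was lost without 72 h PE replicate 2 or 3 or 24 h PBM replicate 1 (0.0815 to 0.129). Gamma, beta AAEL002827 and alpha were also lost with no filter (0.244, 0.275 and 0.0601), gamma and beta AAEL002827 with DESeq2 (0.0544 and 0.0658), and beta AAEL002827 with peaks above the median count (0.0825).

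Among miRNA precursors, reads on mir-305 rose 13.8-fold from 6309 ± 1276 to 86964 ± 17986 CPM (log2 change 3.79, SE 0.32, adjusted p = 9.66e-10, n = 3) and reads on mir-275 6.01-fold from 6362 ± 1108 to 38244 ± 2320 CPM (2.59, SE 0.29, adjusted p 2.60e-07). mir-276-1 (1.75, SE 0.33, adjusted p 0.000216) and mir-281 (2.12, SE 0.43, adjusted p 0.000881) rose too. mir-33 (1.56, adjusted p 0.00341), mir-263a (1.28, adjusted p 0.00627), mir-277 (1.19, adjusted p 0.00500) and mir-283 (1.32, adjusted p 0.0128) rose by TMM but not by library totals (adjusted p of 0.105 to 0.298). They were also lost without 72 h PE replicate 2 (0.0557 to 0.0740), mir-263a and mir-283 without 72 h PE replicate 3 (0.0661 and 0.0668), and mir-283 without 24 h PBM replicate 3 (0.176, log2 change 0.70). With no filter mir-263a was lost (0.0524). Scaled among themselves, 6 of 51 precursors rose and 0 fell, and mir-281 (0.154) and mir-283 (0.325) were no longer called. Precursors of mir-34, mir-8 and mir-184 took the most reads at 72 h PE (3.39%, 2.73% and 2.69% of all counts) and took 3.07%, 2.64% and 1.91% at 24 h PBM.

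Single peaks were compared to place these reads. Of 948 tested peaks, 241 rose and 124 fell (427 at an unadjusted p under 0.05; replicates did not overlap for 448, where chance gives 10%). These counts and the values of single peaks come from the model without pairing (with it, 252 rose and 162 fell). With no filter 300 rose and 13 fell, with library totals 228 and 173, with DESeq2 257 and 83, and without 72 h PE replicate 2 or 3 270 and 81 or 295 and 90. In CDS 202 of 351 rose and 58 fell, in 3′ UTRs 11 of 66 rose and 19 fell, in 5′ UTRs 5 of 18 rose and 3 fell, in introns 1 of 71 rose and 21 fell, and among precursor peaks 4 of 60 rose and 0 fell. A vitellogenin-A1 CDS peak on supercont1.477, 210011 to 210109 on the plus strand (AaegL3), had 0 counts in every 72 h PE library and 40, 27 and 34 counts at 24 h PBM, at least 9.11-fold higher over the floor of 3 counts per library. A uricase CDS peak on supercont1.51, 707667 to 707694 on the plus strand, had 123, 223 and 130 counts at 72 h PE and 26, 15 and 34 at 24 h PBM (log2 change −2.86, SE 0.49, adjusted p = 7.85e-06). A CDS peak of the serine protease AAEL003642 on supercont1.93, 1893401 to 1893426 on the minus strand, had 19, 23 and 19 counts and then 2 in each library (−3.58, SE 0.71, adjusted p 5.76e-05).

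The authors' table of predicted miRNAs, as analysed here, lists 201 loci with miRDeep2 scores from 0 to 209427 (median 2.4), of which 71 score at least 10 and 17 are marked there as documented in earlier publications. The mature sequences had 9 to 410613 reads (median 78), summed over libraries. Of the 201, 24 (11.9%) overlap an AGO1 CLIP-seq peak on their strand by at least 10 bases, and 3 of those have at least 10 CLIP counts, 1 of them a documented one.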

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

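The tests of library scaling, of midgut against other miRNAs, of 1 arm per miRNA, of vitelline membrane counts and of other splits of the libraries were chosen only after the result was seen. The level differed between successive times by edgeR's test for the following miRNAs, as changes in log2 level with an adjusted p under 0.05. From 6 to 24 h PBM the differences were 10.31 for miR-989, 8.91 for miR-2941, 8.25 for miR-286b, 7.94 for miR-2946, 7.0 for miR-2944b-5p, 6.56 for miR-309a, 6.45 for miR-309b-3p and −2.22 for miR-278-5p. Smaller ones were 1.88 for miR-263a-3p, 1.03 for miR-275-3p, −0.99 for miR-124, 0.72 for miR-276-5p, −0.68 for miR-12-3p, 0.60 for miR-305-5p and 0.55 for miR-276-3p. Without single libraries, the calls of miR-12-3p (any 6 h PBM library or 24 h PBM replicate 1 or 2, adjusted p of 0.0564 to 0.158) and miR-124 (6 h PBM replicate 1 or 24 h PBM replicate 1 or 2, adjusted p 0.0699 to 0.114) were lost. With only both compared times in the model, miR-124, miR-276-5p and miR-305-5p (adjusted p 0.0543 for each) and miR-12-3p (0.104) were lost.

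From 24 to 36 h PBM the differences were −3.88 for miR-275-5p, −3.57 for miR-989, 3.45 for miR-2944b-3p, 3.45 for miR-309a, 3.34 for miR-309b-3p, 3.20 for miR-2944b-5p, 2.67 for miR-286a, 2.59 for miR-375, 2.53 for miR-286b and −2.13 for miR-305-3p. They were −1.45 for miR-1, 1.42 for miR-317, −1.27 for miR-34-5p, 1.20 for miR-124, 0.97 for miR-133, −0.87 for miR-71-5p, −0.74 for miR-275-3p, −0.68 for miR-1891 and −0.58 for miR-276-5p. Without single libraries the calls of miR-1 (24 h PBM replicate 3, adjusted p 0.0579), miR-317 (replicate 2 or 3 of either time, adjusted p 0.0505 to 0.0742), miR-133 (24 h PBM replicate 1 or 2 or 36 h PBM replicate 1 or 3, adjusted p 0.0505 to 0.107) and miR-71-5p (any 24 h PBM library, adjusted p 0.0756 to 0.0806) were lost. So were those of miR-275-3p (24 h PBM replicate 1 or 3 or 36 h PBM replicate 3, adjusted p 0.0718 to 0.0774), miR-1891 (any 24 h PBM library or 36 h PBM replicate 1, adjusted p 0.0650 to 0.106) and miR-276-5p (replicate 1 or 3 of either time, adjusted p 0.0553 to 0.0774). With only both compared times in the model, miR-1, miR-34-5p, miR-71-5p, miR-275-3p, miR-1891 and miR-276-5p were lost (0.0601 to 0.163). With library totals miR-71-5p, miR-275-3p, miR-1891 and miR-276-5p were lost (0.0531 to 0.0874), with limma on the deposited RPM miR-276-5p (0.0716), and with no filter miR-275-3p (0.0593). Only miR-286b, miR-2941 and miR-2946 lay below 72 h PE at 6 h and above it at 24, 36 and 48 h PBM, by called changes at all 4 times, and miR-278-5p lay above at 6 h and below at 24 and 36 h PBM.

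Outside the annotated classes, the unannotated CLIP-seq peak with the most counts held 1902 counts over the 6 libraries (890 at 72 h PE and 1012 at 24 h PBM), far above the 3 counts that a count of 0 leaves open. It lies on supercont1.222, 644041 to 644066 on the plus strand (AaegL3), and is 25 bases long. The next such peaks held 1862, 1489, 1443 and 1302 counts.

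Of the 13 tested ovary and embryo miRNAs, 4 fell at 6 h PBM, 6, 8 and 8 rose at 24, 36 and 48 h PBM, and miR-989 fell at 36 h PBM. The list's camera calls were lost at all 4 times (adjusted p = 0.168, 0.300, 0.124 and 0.124 with an estimated correlation). By fry, which compares the list with no other miRNAs, it was called at all 4 times (adjusted p = 0.00211, 0.00147, 0.000113 and 0.000289). A different scaling of the libraries does not account for the rises of miR-286b, miR-309a and miR-2941 at 36 h PBM. Their smallest log2 change over the scalings was 3.71, against a largest shift of the median miRNA of 0.306. These 3 were chosen after their values were seen, and the other members and times were not tested in this way. RNA from ovary tissue in some dissections may account for part of the pattern. Within a time, the 13 members deviated together in the same libraries (mean r of 0.271 against 0.142 at the 95th percentile of random sets, with 3 of 1000 sets as high). With 1 arm per miRNA the mean r was 0.244 (0.166; 8 of 1000). Members made from shared transcripts would also deviate together, so this does not single out ovary tissue, although in CLIP-seq the eggshell gene vitelline membrane 15a-1 had 0, 1 and 2 counts at 72 h PE and 8, 26 and 185 at 24 h PBM. Vitelline membrane 15a-3 had 0 in each library and then 1, 4 and 7. The mir-989 precursor had 3, 6 and 7 and then 14, 20 and 77, and mir-2946 0, 0 and 3 and then 7, 7 and 15. The mir-2945 precursor, also on the list, did not follow (172, 171 and 141, then 239, 159 and 144). The mir-309b and mir-2941-1 precursors and oskar held 6, 1 and 4 counts in all. A change in the fat body itself after the blood meal stays open and was not tested.

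Midgut miRNAs stood high in single libraries, with miR-1174 at 0.138% of the miRNA reads in 48 h PBM replicate 3 and at 0.0588%, 0.0183% and 0.0597% in the 6 h PBM libraries. A few miRNAs taking most of the reads would move all other miRNAs alike. Against 72 h PE by library totals, the 108 other tested miRNAs had a median log2 ratio of 0.19 in 48 h PBM replicate 3 and of 0.17, 0.03 and −0.03 in the 6 h PBM libraries, where the 6 midgut miRNAs had 6.40 and 3.28, 2.05 and 4.13. The smallest gap was 1.40 SD of the other miRNAs, in 6 h PBM replicate 2. In these libraries the other miRNAs therefore did not rise by as much as the midgut ones. However, the 4 libraries were chosen after midgut miRNAs were seen to be high in them. In 48 h PBM replicate 3 the miRNA with 21.3% of the reads, miR-281-5p, is itself a midgut member. The gap thus restates the pattern and cannot exclude this explanation. RNA from midgut tissue in these dissections cannot be told apart from a change in the fat body. The 6 members deviated together (mean r of 0.432 against 0.269 at the 95th percentile; 6 of 1000 sets as high). With 1 arm per miRNA the mean r of 0.263 lay under that percentile (0.384; 145 of 1000), and 4 precursors are too few to decide. Reads on the abundant trypsin genes in CLIP-seq (9, 17 and 16 counts at 72 h PE, 8, 8 and 19 at 24 h PBM) cover neither 6 nor 48 h PBM. A change after the blood meal in the fat body itself was not tested.

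By library totals, 76.0% of the CLIP-seq genes lay lower at 24 h PBM, with a median log2 change of −0.75. A larger share of the counts on risen genes may account for much of this, since the 91 risen genes held 5.05% ± 0.846 of the gene counts at 72 h PE and 37.0% ± 1.73 at 24 h PBM. When these genes were left out the median was −0.14. Scaling to the counts that remain would also hide a fall shared by most genes, so this median does not tell such a fall from the larger share. With them left out, 3 genes rose and 52 fell by library totals, so some falls stand without them. A lower level of these transcripts or less AGO1 on them at 24 h PBM stays open and was not tested, for lack of matched messenger RNA levels here.

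With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so only the real counts and the highest of the other splits are given. These were 14 and 1 at 6 h, 27 and 0 at 24 h, 30 and 0 at 36 h and 28 and 0 at 48 h PBM against 72 h PE. They were 17 and 1 from 6 to 24 h PBM, 20 and 0 from 24 to 36 h PBM, 0 and 0 from 36 to 48 h PBM, 365 and 0 for CLIP-seq peaks and 170 and 0 for CLIP-seq genes. The splits of the CLIP-seq peaks took no account of their pairing by replicate number. Of 100 splits of the 15 small RNA libraries into 5 groups, 1, the real one, gave 54 miRNAs, and the highest other gave 6, so chance is excluded for the test over the 5 times.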

How the results depend on the processing

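Of the alternatives reported here, those on class shares and mean miRNA shares without single libraries, on precursors scaled among themselves, on CDS and UTR peaks, on rRNA peaks and without the 3 most abundant CLIP-seq genes are tests chosen only after the result was seen. The 133 named miRNA results were recomputed under 1991 alternatives in total. Of these, 0 reversed, 81 kept their call in all of them, and 52 lost it in at least 1, with 216 losses in all (138 of them without a single library, 26 with limma on the deposited RPM, 22 with only both compared times in the model and 21 with library totals). The 56 named CLIP-seq results were recomputed under 831 alternatives, 0 reversed, 31 kept their call in all and 25 lost it in at least 1 (106 losses, 68 without a single library, 16 with no filter and 7 with library totals).

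From 36 to 48 h PBM, where edgeR called 0 miRNAs, it called 4 with DESeq2's size factors, 1 with library totals, 2 with no filter, 1 with the 10 CPM filter, 7 with miR-8-3p left out and 13 with the replicate block. DESeq2 called 15 there and limma on the deposited RPM 7. From 6 to 24 h PBM DESeq2 called 26 in place of 17. Library totals called 294 CLIP-seq genes in place of 170 and 2 gene lists in place of 4, and an estimated correlation called 1 list. As a share of peaks in place of counts, the differences at 24 h PBM were −3.92 percentage points for CDS and 0.666 for introns, both reversed, and −0.418 for 3′ UTRs. A score of at least 10 left 71 of the 201 predicted miRNAs. Except for the composition of CLIP-seq counts, the cause was not tested.

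Leaving out 1 library gave 10 to 15 miRNAs at 6 h, 19 to 28 at 24 h, 22 to 37 at 36 h and 20 to 35 at 48 h PBM, 15 to 21 from 6 to 24 h, 14 to 24 from 24 to 36 h and 0 to 4 from 36 to 48 h PBM (4 without 48 h PBM replicate 1, 1 without 36 h PBM replicate 1). It gave 39 to 62 over the 5 times, 11 to 12 list calls, 331 to 438 peaks, 125 to 199 CLIP-seq genes and 4 to 5 gene lists. The class differences ranged from 3.65 to 6.59 for CDS, −1.71 to −1.13 for 3′ UTRs, −0.428 to −0.144 for 5′ UTRs, −2.67 to −1.87 for introns and 0.725 to 4.72 for miRNA precursors. The 5′ UTR difference of −0.253 was −0.428 without 72 h PE replicate 1 and −0.144 without 24 h PBM replicate 1.

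In the small RNA libraries 21 of the 30 pairs with the same replicate number correlated above 0.1 (range −0.738 to 0.542), and 13 of 15 libraries correlated best with their own number, a hint from the data and not from the design. With the replicate block 32 miRNAs were called from 24 to 36 h PBM in place of 20, 44 at 36 h in place of 30 and 42 at 48 h PBM in place of 28, and 3 named calls, miR-1174, miR-1175-3p and miR-1175-5p at 48 h PBM, were lost (adjusted p of 0.0680 to 0.0926). The block changed no named CLIP-seq call and gave 205 CLIP-seq genes in place of 170. Of the alternatives chosen at the start, those on seed matches were not run, and those on a pseudocount or a peak overlap had no result to change. Counting depth limits low miRNAs (0.475 to 1.42 CPM for a count of 0) and CLIP-seq peaks (22.6 to 43.2 CPM). For CLIP-seq genes this limit lies higher.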

Other observations

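The tests of AGO1 against small RNA levels and of undocumented predictions were chosen only after the result was seen. Several further groups of miRNAs were measured. Of 8 neural miRNAs 1, 1, 0 and 0 rose and 0, 1, 3 and 3 fell at 6, 24, 36 and 48 h PBM (1 rose and 3 fell at 48 h adjusted over the list alone; camera adjusted p = 0.769, 0.386, 0.299 and 0.378), the 3 being miR-9 family members. Of 3 members of the let-7 complex, which times development, 1 (miR-125-5p) fell at 48 h PBM and 0 changed before (2 fell at 48 h adjusted over the list alone; camera adjusted p 0.603, 0.591, 0.338 and 0.188). Of the 5 members of the miR-277 cluster 2 rose at 24 h (miR-34-5p and miR-277-5p) and 1 at 36 h PBM (miR-317), and 2 fell at 6 h when adjusted over the list alone (camera adjusted p 0.749, 0.777, 0.949 and 0.928). Of the 8 of the miR-2 cluster 1 (miR-71-5p) rose at 24 h PBM (camera adjusted p 0.997, 0.749, 0.980 and 0.947), and of the 3 of the miR-12 cluster 1 (miR-12-3p) rose at 6 h (camera adjusted p 0.558, 0.928, 0.763 and 0.636), with the same counts adjusted over the list alone. Of 9 metabolism-linked miRNAs 2 rose at 6 h (miR-8-5p and miR-278-5p), 1 fell at 24 h, and 1 rose and 1 fell at both 36 and 48 h PBM (1 and 2 at 48 h adjusted over the list alone; camera adjusted p 0.634, 0.481, 0.426 and 0.378). Of the muscle pair miR-1 and miR-133, too few for a set test, miR-1 rose at 24 h PBM, and adjusted over the list alone 0, 1, 1 and 2 rose. Median and mean log2 changes differ in sign for the neural list at 6 h (−0.05 and 0.22), the metabolism list at 6 h (−0.04 and 0.13) and the miR-2 cluster at 24 h (−0.14 and 0.07) and 48 h PBM (−0.06 and 0.10). That cluster's median of −0.15 and mean of −0.01 at 6 h go with a test pointing up, and its median of 0.12 at 36 h with a test pointing down. With an estimated correlation 2 of the 44 list tests were called in place of 12, and by fry, which compares a list with no other miRNAs, 18, or 22 for changes in either direction.

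In AGO1 CLIP-seq, E74 and E75 rose among the 4 tested hormone pathway genes (20 measured; 2 adjusted over the list alone; camera adjusted p = 0.179). Pyruvate kinase (AAEL012576, log2 change 1.86, SE 0.53, adjusted p = 0.0110) was the 1 riser of 7 tested carbohydrate genes (18 measured; 1 adjusted over the list alone; camera adjusted p 0.910), lost with library totals (0.122), with no filter (0.120) and without 72 h PE replicate 3 (0.0682). Of 10 tested muscle genes (42 measured; camera adjusted p 0.235) 1 rose, also adjusted over the list alone, a nonmuscle myosin heavy chain (AAEL005733, 1.47, SE 0.38, adjusted p 0.00610), which works in all cells, lost with library totals (0.155) and without 72 h PE replicate 2 (0.0521). Fatty acid synthase was the 1 of 4 tested lipid genes (57 measured; camera adjusted p 0.235) that fell, also adjusted over the list alone. Of 4 tested immune genes (102 measured; camera adjusted p 0.496), prophenoloxidase rose and a serpin (AAEL013936, −1.41, adjusted p 0.0237) fell, with 2 and 1 adjusted over the list alone, and the serpin was lost without 24 h PBM replicate 1 or 72 h PE replicate 2 or 3 (0.0530 to 0.0688), with no filter (0.140), with peaks above the median count (0.0501) and with CDS and UTR peaks only (0.0875). The other lists held too few tested genes for a set test. A sugar transporter (AAEL000902, −1.66, adjusted p 0.0261), the 1 tested of 47 nutrient transport genes, fell, also adjusted over the list alone, but was lost without any of the 6 libraries (0.0755 to 0.108), with no filter (0.373) and with DESeq2 (0.0682). The insulin-like receptor, the 1 tested of 5 insulin and TOR genes, changed by 1.15 (adjusted p = 0.132; 1 rose adjusted over the list alone), and 2 tested of 39 secretory and chaperone genes had a median of −1.04 (0 called; 2 fell adjusted over the list alone). For neural (1 tested of 15) and cuticle genes (1 of 11) 0 were called, also adjusted over the list alone, and 0 of 27 proteasome, 3 hexamerin, 12 gut digestion and 3 ovary genes had enough counts to be tested. Counts per library on the ovary list averaged 1 at 72 h PE and 78.3 at 24 h PBM, and on gut digestion genes 14 and 11.7.

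The hypothesis that AGO1 binding follows miRNA levels predicts that changes in both assays at 24 h PBM go together. Over 51 miRNAs, which are not independent replicates, Spearman's rho of the log2 changes was 0.36 (two-sided permutation p = 0.0112) and Pearson's r was 0.376 (p = 0.0101). Without miR-275 and miR-305, rho was 0.284 and r 0.160, so the relation may rest in part on these. Of 6 miRNAs called in CLIP-seq and 13 in small RNA, each summed over arms and scaled among themselves, 4 rose in both. The shares of the 51 in both assays went together (rho of 0.470, two-sided permutation p = 0.00061), although miR-8 held 57.2% of these small RNA reads and 12% of the CLIP-seq reads, and miR-34 0.562% and 14.5%.

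If predicted miRNAs are bound by AGO1, their precursors should overlap CLIP-seq peaks more often than shifted positions do. Of the 201, 24 overlapped, against a median of 2 and a highest of 7 over 100 random shifts of 1000 to 10000 bases, which is consistent with AGO1 on some of them, although only 3 held at least 10 counts. The authors' deposited table marks 17 of the 201 as already documented, among them 3 of the 24 and 1 of the 3 with at least 10 counts. Of the 184 others 21 overlapped, against a median of 1.5 and a highest of 6.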
